A study of Homo sapiens with 10 samples.

How the data were processed

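Gene expression was measured on 10 Affymetrix human expression arrays, 1 for each combination of 2 non-small cell lung cancer cell lines and 5 treatments. Group membership was taken from the sample source descriptions in the labels. The labels are not fully consistent, as the titles of the estradiol plus tamoxifen arrays name only tamoxifen and the source descriptions of the A549 arrays join the names of both lines, while their cell line entries read A549. No replicate cultures are stated, so every combination of line and treatment is a single array. All p-values measure the spread between these arrays, which may be technical or a difference in response between the lines. Per the labels' protocols, total RNA was isolated on columns and labelled by the array manufacturer's protocol. The values are intensities on a linear scale that the authors deposited as a single table for the series, and MAS5 is the only program in the submitters' processing notes. Its version and its scaling target are not given in the sources used here. The mean intensity of an array after trimming 2 percent at each end ran from 105.86 to 115.684, a 1.09-fold range, so the arrays had not been brought to exactly the same trimmed mean over all probe sets.

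The table held 54675 probe sets, of which 62 are manufacturer's controls and were left out of the tests. Of the others, 41091 name 1 gene in the platform annotation, 1801 name several and 11721 name none here, and only those with 1 gene were used. Symbols were compared through gene numbers with a RefSeq gene table, which held 41037 of the 1-gene probe sets and required 0 changes of symbol. Each of the 19775 genes was represented by its brightest probe set. Intensities were transformed as log2(intensity + 16), so fold changes are on that scale and understate the change of dim genes. Genes whose mean log2 value was at or above the median over all probe sets were kept, which corresponds to an intensity of 19.7 and left 12979 genes.

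Differences were estimated with limma (version 3.58.1) in R (version 4.3.3), using moderated statistics with an intensity trend and Benjamini-Hochberg adjustment at 0.05. The additive model held the cell line and the treatment and left 4 residual degrees of freedom. Its spread is made of the differences between the lines in their response to treatment. A response of 1 line alone therefore adds to the spread. A treatment count of 0 means that no change common to both lines stood out from it. The additive model gave the tamoxifen effect over both estrogen forms from 4 pairs of arrays, each treatment against vehicle and estradiol-BSA against estradiol from 2 pairs, and the line difference from 5 pairs. Another model added a cell line by tamoxifen term (3 residual degrees of freedom), and the last also a cell line by estrogen term (2 residual degrees of freedom). The estrogen term compares estradiol and estradiol-BSA, without tamoxifen, with vehicle. In the model with the tamoxifen term the line term also draws on the vehicle arrays, so an estimate for 1 line can lie outside the range of its own pairs. Within a line, a treated array against a vehicle array has no replicate, and such differences are given as sizes without a p. The cell line by estrogen term compares such differences between the lines. Its model fits each vehicle array exactly, so its p rests on the spread of the treated arrays and on the assumption that the lone vehicle arrays vary like them. The cell line entered every model as the block that pairs the arrays, because arrays of a pair come from the same line.

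For each tested comparison the named genes were chosen by a rule. It takes up to 12 higher and 12 lower genes of largest change that passed the threshold and moved the same way in every pair. Where fewer than 10 genes passed, it also takes up to 10 genes in each direction that were at least 1.5-fold apart the same way in every pair, given as values. It adds up to 4 members of each gene list and the receptor genes ESR1, ESR2, GPER1 and PGR. The 23 gene lists were tested with camera from limma at a preset correlation between genes of 0.01, and again with the correlation estimated from the residuals. The lists were classical estrogen targets, estrogen receptors and partners, immediate early genes, integrated stress response, unfolded protein response chaperones, heat shock response, sterol synthesis and uptake, liver X receptor targets and fatty acid synthesis, aryl hydrocarbon receptor targets, NRF2 targets, NF-kB and cytokine genes, p53 targets, G1/S and replication genes, G2/M genes, apoptosis regulators, hypoxia and glycolysis genes, glucocorticoid receptor targets, autophagy and lysosome genes, and markers of squamous, alveolar and adenocarcinoma, mesenchymal, blood and endothelial, and neuroendocrine cells. List members were also counted after adjustment over the list alone. Within a line, a list's median was placed among 10000 random lists of genes of like expression, which treats genes as independent and describes 2 arrays only.

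The models, lists, rule for named genes and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 1 and 64, no filter or an upper quartile filter on signal, quantile normalization, the mean over probe sets, every probe set alone, no intensity trend, models without the cell line or without the treatment, paired differences, a 1.5-fold limit, and leaving out each array. With 1 array per line and treatment, a fit without an array leaves its treatment with the array of the other line, which is then fitted exactly and assumed to vary like the others. For comparisons that use no vehicle array, the fits without either vehicle array thus share the spread of the treated arrays. They are not separate checks. Array quality weights and centring of each array on its median were added after the data were seen, and so were the bounds for named genes, for which values below the filter intensity were raised to it before the fit.

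The procedure was tested on simulated data, in which 200 of 12979 genes were changed by known amounts. Of genes changed 2-fold, 100% were recovered for the tamoxifen effect, 94.4% for estradiol against vehicle, 93.6% for estradiol-BSA against estradiol, 98.4% for tamoxifen in HTB-182 and 52.8% for the cell line by estrogen term. At 1.41-fold these shares were 68%, 22.8%, 19.6%, 29.2% and 9.2%. The mean number of false calls in these runs was 12.6, 14.2, 10, 17.4 and 5, or 6.41%, 8.24%, 6.00%, 9.61% and 3.73% of all calls, so the share could exceed the nominal 5%. With each line given its own spread, the cell line by estrogen term recovered 72% at 2-fold with 15.8 false calls, 10.1% of all calls. With no gene changed and each line given its own spread, the mean number of false calls was 0 for the tamoxifen effect, 0.2 for estradiol against vehicle, 0.6 for the line difference, 0.8 for the cell line by estrogen term and 1.8 for the cell line by tamoxifen term. The spread of a line came from its treated arrays and was given to its vehicle array too. The real A549 vehicle array lay a median of 0.252 log2 units from the mean of the treated A549 arrays, whose median SD was 0.136. These runs thus do not cover false calls that come from that array. In a simulated shift of 0.2 log2 units, camera called the shifted list in 20 of 20 runs with the preset correlation and in 11 of 20 with the estimated correlation. The simulated genes were independent, which is close to the preset correlation. In the data the estimated correlation of the lists called in treatment comparisons ran from -0.0054 to 0.36. The runs therefore do not show how camera with the preset correlation behaves for correlated lists. The number of arrays limits the precision.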

Results

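The series asked which early transcriptional effects of estrogen in non-small cell lung cancer cells start at the plasma membrane. HTB-182 is a squamous carcinoma line, called H520 in the series title, and A549 is an adenocarcinoma line. Each line was kept for 4 h in medium with charcoal-stripped serum and then exposed for 3 h to ethanol vehicle (0.1%), 1 µM estradiol, or 1 µM estradiol coupled to bovine serum albumin (estradiol-BSA). The conjugate was used for signals of membrane receptors, and free estradiol for intracellular and membrane receptors together. Both estrogen forms were also given with 10 µM tamoxifen, used as an inhibitor. The source descriptions name no array with albumin alone or tamoxifen alone. Every combination of line and treatment was 1 array, 10 in all, with median intensities of 17.5 to 21.4 per array. The titles of the arrays given estradiol and tamoxifen name tamoxifen alone, while their source descriptions name both compounds, which were followed here. If no estradiol was given, comparisons that use these arrays would have another meaning.

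The cell line accounted for most of the variance between arrays, as the first principal component held 92.7% of it and parted A549 from HTB-182. Arrays of HTB-182 correlated with each other across genes at r = 0.996 or above, and those of different lines at 0.775 to 0.789. Genes are not independent replicates, so these correlations carry no p. Within A549 the vehicle array stood apart, with 263 genes at least 2-fold from the mean of the other A549 arrays. On the other A549 arrays this number was 23 to 35, and in HTB-182 it was 0 to 3.

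**Figure D1:**
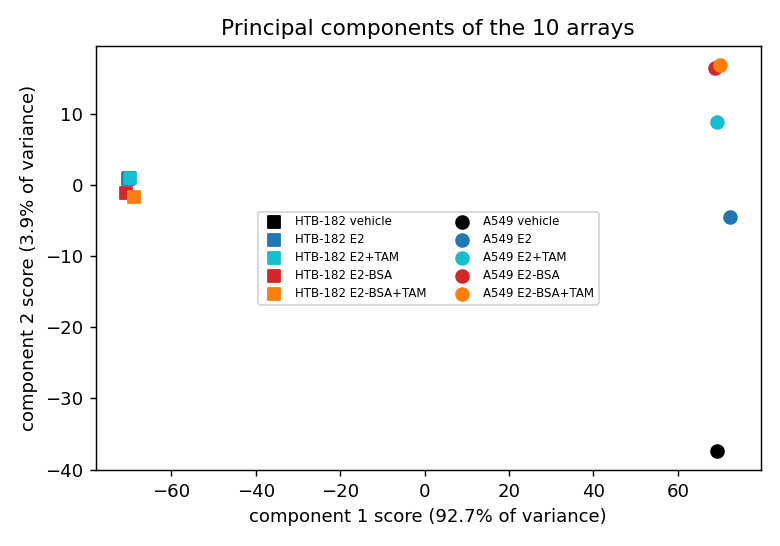
Scores of the 10 arrays on the first principal component (92.7% of variance, x axis) and the second (3.90%, y axis), with 1 point per array, a marker shape for each line and a colour for each treatment. The HTB-182 points overlap on the left, and the A549 vehicle array lies at -37.4 on the second component, below the other A549 arrays.

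By their brightest probe sets the estrogen receptor genes were close to the level below which genes were left out, an intensity of 19.7. ESR1, encoding estrogen receptor alpha, had an intensity of 20.3 ± 3.69 (SD, n = 5 arrays) in HTB-182 and 23.0 ± 3.18 in A549. ESR2, encoding estrogen receptor beta, had 27.8 ± 1.49 and 28.2 ± 9.40, and GPER1, encoding the G protein-coupled estrogen receptor, had 23.4 ± 5.07 and 24.7 ± 3.96. All other probe sets of these genes had means below 19.7 in both lines. They reached at most 17.4 for ESR1, 12.5 for ESR2 and 6.76 for GPER1. The dimmest ESR1 probe set was at 3.41 in HTB-182 and 3.76 in A549. The values of the receptor genes thus rest on the brightest probe set alone and do not show that these genes were expressed. The progesterone receptor gene PGR, a classical estrogen target, was below 19.7 and was not tested. By limma, A549 minus HTB-182 was 0.11 on the log2 scale for ESR1 (adjusted p = 0.217, positive in 4 of 5 pairs) and 0.05 for GPER1 (adjusted p = 0.572, positive in 3 of 5). For ESR2 it was -0.0090 (adjusted p = 0.949), and its sign turned with a pseudocount of 64. After estradiol the log2 difference from vehicle was -0.18 for ESR1, -0.32 for ESR2 and -0.15 for GPER1, with adjusted p of 0.913, 0.913 and 0.914. The ESR2 pairs were unequal, at -0.03 in HTB-182 and -0.62 in A549. In a fit without the HTB-182 vehicle array, where vehicle is the A549 array alone, ESR2 was at -0.63 (adjusted p = 0.0282, and up to 0.999 without other arrays).

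Free estradiol was compared with vehicle to find its early targets. The genes at least 1.5-fold higher in both lines were ABCD4, encoding a lysosomal cobalamin transporter, and CAVIN1, encoding a coat protein of caveolae, where independent lists give 0.977. ABCD4 was 1.74-fold higher than with vehicle (log2 0.80 ± 0.19, SE, 2 pairs; 0.67 and 0.93 in the pairs), and CAVIN1 was 1.64-fold higher (0.71 ± 0.23; 0.61 and 0.82). The mean for FAS, a death receptor gene, was 2.14-fold higher, but its pairs were 0.01 in HTB-182 and 2.19 in A549, where it rests on the vehicle array that stood apart, and its other 3 probe sets had a median of 0.09. BAX, a pro-apoptotic gene of the p53 targets, was at 0.70 and the autophagy gene ATG16L1 at 0.76, again with unequal pairs (0.11 and 1.29, 0.18 and 1.34), and the other probe set of BAX was at 0.09. All had an adjusted p of 0.913, and 0 of 12979 genes passed at 0.05 with limma, while 581 had an unadjusted p under 0.05 against 648.95 given by chance.

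Among the gene lists, unfolded protein response chaperones were the only list called after estradiol, higher than other genes by camera with the preset correlation (adjusted p = 0.0141; median log2 0.08, 14 of 21 members above 0). With an estimated correlation the adjusted p was 0.933. In A549 their median was 0.11 (percentile 98.7 among random lists) and in HTB-182 0.01 (percentile 62.3). Classical estrogen targets were not called (adjusted p = 0.312; 14 of 33 above 0), and the test's direction was upward while their median was -0.02 and their mean 0.04. No member of either list passed over all genes or adjusted over the list alone, with smallest values of 0.428 and 0.578.

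Between single arrays, 243 genes were at least 2-fold higher and 15 lower after estradiol in A549, whose vehicle array stood apart from its line in 263 genes (249 of them lower). In HTB-182 the counts were 4 and 1, with 0 shared in either direction (0.0749 and 0.00116 given by independent lists). The median size of the change from vehicle was 0.0916 on the log2 scale in HTB-182 and 0.211 in A549. In pairs without a vehicle array it was 0.0974 and 0.211 between the estrogen forms and 0.0824 and 0.183 for tamoxifen on estradiol, but 0.0885 and 0.0924 for tamoxifen on the conjugate. Without the HTB-182 vehicle array 1078 genes passed by limma, in a fit in which vehicle is the A549 array alone, among them ABCD4 (adjusted p = 0.0095), CAVIN1 (0.0252), ATG16L1 (0.00499), BAX (0.00966) and FAS (log2 1.93, adjusted p = 0.000266). Over all arrays left out these genes ran up to 0.999. Without the A549 vehicle array, when vehicle is the HTB-182 array alone, 1 gene passed, IFIH1 (log2 1.21, adjusted p = 0.0298), named after its values were seen.

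**Figure D2:**
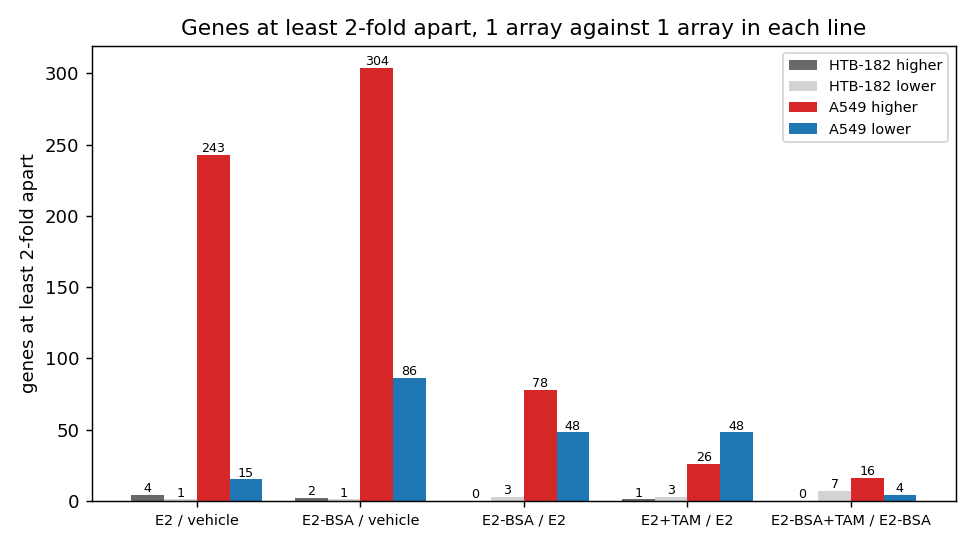
Numbers of genes at least 2-fold apart (y axis) between single arrays in 5 comparisons (x axis), with bars for genes higher or lower in HTB-182 and in A549. The A549 bars against vehicle, 243 and 304 genes higher, are the tallest, and the HTB-182 bars stay at 7 genes or fewer.

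The conjugate was compared with vehicle to look for signals of membrane receptors. With no array of albumin alone, an effect of the albumin cannot be told apart from one of the coupled estradiol. ID1, encoding an inhibitor of basic helix-loop-helix transcription factors, was 2.09-fold lower with estradiol-BSA (log2 -1.06 ± 0.15, SE; -1.06 in both pairs; adjusted p = 0.331). It was the 1 gene at least 2-fold lower in both lines, where independent lists give 0.00663, and none was 2-fold higher in both. The ubiquitin ligase gene MARCHF4 (-0.80), the noncoding RNA SPRY4-IT1 (-0.77) and the actin regulator MICAL3 (-0.62, its other probe sets at -0.13) were at least 1.5-fold lower in both lines, and ABCD4 (0.74) was at least 1.5-fold higher. DUSP6, a phosphatase that acts on ERK, was at -0.46 with its other probe sets at -0.47, and the ETS factor gene ETV5 was at -0.44 with its other probe sets at -0.14. SLC1A5, a glutamine transporter gene, was at -0.48. Of NRF2 targets, UGDH was at 0.39 and GSR at 0.41, with the other probe set of GSR at -0.02. Except for ID1 these had an adjusted p of 0.665.

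Immediate early genes had a median of -0.14 with estradiol-BSA, and 25 of 34 members lay below 0. Camera did not call them (adjusted p = 0.452, and 0.997 with an estimated correlation), and no member passed over all genes or adjusted over the list alone (smallest 0.17). In HTB-182 their median of -0.12 was below that of all 10000 random lists, and in A549 -0.20 was at percentile 59.2. By limma 0 genes passed and 840 had an unadjusted p under 0.05. Without the HTB-182 vehicle array 2058 passed, again with vehicle resting on the A549 array alone, among them ID1 (adjusted p = 0.000457, and up to 0.9999 without other arrays). MARCHF4 (0.00661), ABCD4 (0.00941), UGDH (0.0121), GSR (0.016), MICAL3 (0.0261), SPRY4-IT1 (0.0369) and ETV5 (0.0427) passed there too, and they also ran up to 0.9999. In single arrays 304 genes were at least 2-fold higher and 86 lower in A549, again against the vehicle array that stood apart, and 2 and 1 in HTB-182.

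Estradiol-BSA differs from free estradiol by the protein coupled to the steroid, and both were given at 1 µM for 3 h. ID1 was 2.07-fold lower with the conjugate (log2 -1.05 ± 0.15, SE, 2 pairs; 95% interval -1.38 to -0.72; adjusted p = 0.354). Its pairs were -1.33 in HTB-182 and -0.78 in A549. The smooth muscle actin gene ACTA2 was at -0.72 and the stress-responsive gene NDRG1 at -1.17, the latter with pairs of -0.32 and -2.01. Higher with the conjugate were YIPF4 (0.83, its other probe set at 0.14) and GPER1 (0.38, interval 0.11 to 0.64), whose signal lay close to the filter intensity. These 4 had an adjusted p of 0.993. The related genes ID2, ID3 and ID4, chosen after their values were seen, were at -0.58, -0.36 and -0.11 in HTB-182 and at -0.85, -1.19 and -1.14 in A549.

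Between the estrogen forms 0 genes passed by limma, and 454 had an unadjusted p under 0.05. The missed threshold does not show that the forms act alike. The 95% interval reached a median of 1.28-fold to either side, and for 97.9% of genes it lay within 2-fold. Unfolded protein response chaperones were lower with the conjugate than with free estradiol by camera (adjusted p = 0.00277; median -0.14, 15 of 21 below 0). With an estimated correlation the adjusted p was 0.957, and 0 members passed over all genes or adjusted over the list alone. Their median was -0.28 in A549 and 0.0047 in HTB-182. The call of this list as higher after estradiol also came mainly from A549. Both calls share the A549 estradiol array and are not independent. That array lay at -4.58 on the second principal component, and the other treated A549 arrays at 8.81 to 16.8. By limma ID1 passed without the HTB-182 vehicle array and without the A549 vehicle array, at a log2 of -1.05 in both fits. It also passed with array quality weights (adjusted p = 0.0337). These are not separate checks, as both fits take their spread from the same estrogen arrays. The weights of both vehicle arrays were 0.313, the lowest of all arrays. Over the other settings the adjusted p of ID1 ran from 0.0337 to 1, and without any other array ID1 did not pass.

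**Figure D3:**
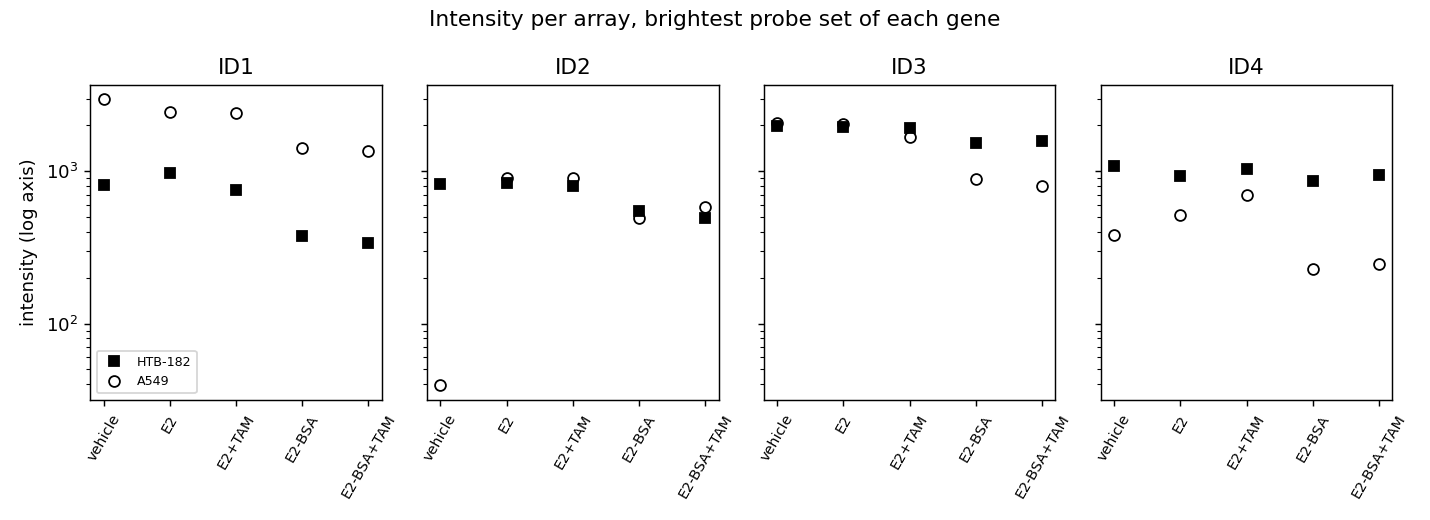
Intensity (y axis, log scale) of ID1, ID2, ID3 and ID4 on each array by treatment (x axis), with filled markers for HTB-182 and open markers for A549. ID1 in HTB-182 lies at 972 and 758 on the free estradiol arrays and at 378 and 337 on the conjugate arrays, and ID2 lies at 39.4 on the A549 vehicle array.

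Estradiol with tamoxifen was also compared with vehicle. INSIG1, which restrains sterol synthesis and is itself sterol-regulated, was 1.83-fold higher (log2 0.87 ± 0.19, SE; 0.42 and 1.32 in the pairs; other probe sets at 0.25), and the sterol synthesis enzyme gene MSMO1 was 1.37-fold higher (0.45 ± 0.11). Both passed when adjusted over the list alone (2 of 19 sterol genes, smallest adjusted p 0.0139), and not over all genes (adjusted p = 0.786). The chaperone gene DNAJB9 was at 0.47 with other probe sets at 0.70, and HERPUD1, of endoplasmic reticulum degradation, was at 0.45. Lower values were those of EPHX1 (-0.79), GET3 (-0.77), PLAU (-0.73), GPX3 (-0.64, its other probe set at -0.18) and SLC1A5 (-0.61). The limma count was 0 genes, 594 had an unadjusted p under 0.05, and no list was called (smallest adjusted p 0.115). Without the HTB-182 vehicle array 1754 genes passed, again with vehicle resting on the A549 array alone. Among them were INSIG1 (adjusted p = 0.000454), HERPUD1 (log2 0.71, adjusted p = 0.00598), MSMO1 (0.0306), GET3 (0.0342) and SLC1A5 (0.0487), all up to 0.9999 without other arrays. Without the HTB-182 array of estradiol with tamoxifen, when that treatment is the A549 array alone, 1 passed, NEMP1 (adjusted p = 0.0143), named after its values were seen.

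With estradiol-BSA and tamoxifen ID1 was 2.26-fold lower than with vehicle (log2 -1.17 ± 0.15, SE; adjusted p = 0.132; -1.22 and -1.13 in the pairs). The linker histone gene H1-2 (-0.96), the splicing factor gene SRRM2 (-0.83), RABL6 (-0.80), HIP1 (-0.75) and the transcription factor gene HAND1 (-0.63) were lower in both lines at an adjusted p of 0.653. The other probe set of HIP1 was at 0.19, in the opposite direction, and those of SRRM2 and RABL6 had medians of -0.20. INSIG1 was at 0.68, with its other probe sets at -0.08, ABCD4 at 0.72 and UGDH at 0.35. By limma 0 genes passed, 962 had an unadjusted p under 0.05, and no list was called (smallest adjusted p 0.19). Without the HTB-182 vehicle array 2104 genes passed, again with vehicle resting on the A549 array alone, among them ID1 (adjusted p = 0.000177, and up to 0.478 without other arrays). H1-2 (0.00114), INSIG1 (0.00182), HAND1 (0.00942), ABCD4 (0.0102), RABL6 (0.015), UGDH (0.0178), SRRM2 (0.0268) and HIP1 (0.0308) passed there too, and they ran up to 0.9999.

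The effect of adding tamoxifen was estimated over both estrogen forms from 4 pairs of arrays. Sterol synthesis and uptake genes were higher with tamoxifen by camera (adjusted p = 0.0322; median log2 0.06, 14 of 19 above 0), led by INSIG1 (0.39 ± 0.13, SE; 0.17 to 0.70 over the pairs; other probe sets at 0.14) and MSMO1 (0.29 ± 0.08; 0.15 to 0.41). G1/S and replication genes were lower (adjusted p = 0.0183; median -0.09, 19 of 25 below 0). With an estimated correlation the adjusted p was 0.944 for both lists, and 0 members passed over all genes or adjusted over the list alone (smallest 0.0813 and 0.76). DNAJB9 (0.31), the co-chaperone gene BAG3 (0.29), DUSP6 (0.28, its other probe sets at 0.12) and CHAC1 (0.25), a gene of the integrated stress response, were higher in 4 of 4 pairs, with an adjusted p of 0.9998. Of all genes 0 passed by limma and 151 had an unadjusted p under 0.05. The 95% interval reached a median of 1.19-fold to either side and lay within 2-fold for 99.7% of genes.

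Whether tamoxifen acted differently on the 2 estrogen forms was tested as their difference. The extracellular matrix gene OLFML2A (log2 1.04 ± 0.30, SE) and ACTA2 (0.92 ± 0.28) had larger values with the conjugate, and PGBD5 (-0.89), SNX29 (-0.84) and GPER1 (-0.52) smaller ones, each in 2 of 2 lines. The other probe set of SNX29 was at 0.03. None passed by limma (0 genes, adjusted p of 1 for these), 116 had an unadjusted p under 0.05, and no list was called (smallest adjusted p 0.128).

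In HTB-182, WASF3, encoding an actin regulator, had intensities of 359 and 405 with estradiol and estradiol-BSA, 125 and 121 when tamoxifen was added, and 170 with vehicle. The collagen prolyl hydroxylase gene P3H1 was at 239 and 242, then 95.4 and 106, with 154 for vehicle. Their tamoxifen effects in the pairs were -1.41 and -1.62 for WASF3 and -1.19 and -1.08 for P3H1. The cyclin gene CCNG2 was at 0.78 with its other probe sets at 0.36, and the growth factor gene ARTN at 0.79, while the other 2 probe sets of ARTN had a median of -0.08. By limma 0 genes passed (adjusted p = 0.9998 for these genes) and 124 had an unadjusted p under 0.05. Without the HTB-182 vehicle array or the A549 vehicle array 3 passed, WASF3, P3H1 and LRRN1, with adjusted p for WASF3 of 1.2e-07 and 4.6e-07. Over all arrays left out WASF3 ran up to 1. Without the HTB-182 array of estradiol with tamoxifen 2 passed, KIF26B and KIT (adjusted p = 0.013 for both). That fit has 1 HTB-182 array with tamoxifen and matches every tamoxifen array exactly, so its spread comes from the other arrays and the lone array is assumed to vary like them. LRRN1, KIF26B and KIT were named after their values were seen. The fits without either vehicle array share the spread of the treated arrays and are not separate checks.

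The lists called for tamoxifen in HTB-182 numbered 3, each at an adjusted p of 0.0412 and at 0.896 with an estimated correlation. Sterol genes were higher (17 of 19 above 0), immediate early genes were higher (27 of 34 above 0) and G1/S and replication genes were lower (14 of 25 below 0). No member passed over all genes or adjusted over the list alone (smallest 0.401, 0.812 and 0.962). Immediate early genes had a median of 0.14 when tamoxifen was added to estradiol-BSA, at percentile 100 of the random lists, with 30 of 34 above 0. This rise and their fall with estradiol-BSA against vehicle share the HTB-182 estradiol-BSA array. Sharing that array alone gives r = -0.504 across genes between these differences by simulation, and the observed r was -0.421. The opposite directions are therefore no independent check of each other.

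In A549, TRIP6, encoding a focal adhesion adaptor, had intensities of 176 and 189 with estradiol and estradiol-BSA, 47.7 and 84.6 when tamoxifen was added, and 152 with vehicle. RRAS, encoding a small GTPase, was at 448 and 321, then 135 and 157, with 110 for vehicle. TRIP6 was at -1.59 and -1.03 in the pairs (adjusted p = 0.253), and the nuclear protein gene CSRNP1 at -1.05 and -0.97. INSIG1 was at 0.64 in the fit, with its other probe sets at 0.20, and was the 1 of 19 sterol genes that passed adjusted over the list alone (0.0203). Of all genes 0 passed by limma, 335 had an unadjusted p under 0.05, and no list was called (smallest adjusted p 0.41). The count was 19 without the HTB-182 vehicle array and 19 without that of A549, with adjusted p for TRIP6 of 5.0e-06 and 3.3e-06 (up to 0.9998 without other arrays). It was 30 without the A549 array of estradiol-BSA and 1 (NCKAP1) without that of HTB-182, when the conjugate alone is 1 array of the other line. It was 3 (NEMP1, PDE4B and PPP1R14A) without the A549 array of estradiol-BSA with tamoxifen. That effect then rests on 1 A549 array with tamoxifen, and the spread comes from the arrays without it. These 4 genes were named after their values were seen. Here too the fits without either vehicle array share their spread and are not separate checks.

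The difference between the lines in the tamoxifen effect was tested directly. A549 minus HTB-182 was -1.26 ± 0.24 (SE, log2) for TRIP6, -1.03 for CSRNP1, 1.10 for WASF3 and 0.84 for P3H1, at an adjusted p of 0.971 for each. By limma 0 genes passed and 260 had an unadjusted p under 0.05, and no list was called (smallest adjusted p 0.74). Without the HTB-182 vehicle array or the A549 vehicle array 3 passed, TRIP6 (adjusted p = 0.00167 and 0.00129), WASF3 and RRAS. Over all arrays left out TRIP6 ran up to 0.9998, and over the other settings from 0.00632 to 0.998. Without the HTB-182 or the A549 array of estradiol-BSA, which leaves 1 array of the conjugate alone, 4 others passed, ACTL6A, NCKAP1, PRKAR1A and RAD21, named with RRAS after their values were seen. With array quality weights 105 passed. These weights were equal for both lines within a treatment, at 0.376 for vehicle, 4.52 for estradiol and 0.323 for estradiol-BSA. They thus weight whole treatments and do not part the A549 vehicle array from that of HTB-182. The fits without either vehicle array share their spread and are not separate checks.

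The response to estrogen without tamoxifen was compared between the lines, and 369 genes passed by limma, 289 with a higher and 80 with a lower value in A549, while 2077 had an unadjusted p under 0.05. Each line has 1 vehicle array, which this model fits exactly, so the spread came from the treated arrays alone and the lone vehicle arrays were assumed to vary like them. The p-values do not allow for the A549 vehicle array standing apart from its line (263 genes). The median over all genes was -0.15. Of the genes with an unadjusted p under 0.05 by limma, 756 had a higher and 1321 a lower value in A549, the opposite balance to the calls. ID2 had the largest difference (log2 3.90 ± 0.26, SE, 15.0-fold; adjusted p = 7.2e-15), with an intensity of 39.4 on the A549 vehicle array against 491 to 901 on the other A549 arrays. ITSN2, encoding an endocytic scaffold, was at 15.0 there, below the filter intensity, against 359 to 424 (3.70, adjusted p = 1.2e-12, and 3.50 with that array raised to the filter intensity), and the phosphatase subunit gene PPP6C at 31.5 against 450 to 481 (3.34). PHTF2 (3.37, or 3.30 when raised likewise), FUNDC1 (3.18), NECTIN3 (3.11), CYB5B (2.89) and TFAP2A (2.69) followed. ERBB2, encoding the HER2 receptor, had the most negative difference of the named genes (-1.85, adjusted p = 0.00111), before ZNF544 (-1.45), NMNAT3 (-1.42) and NSUN5 (-1.26). Other probe sets of ID2, ITSN2, PPP6C, PHTF2, NECTIN3 and CYB5B had medians of -0.23 to 0.13, and those of ZNF544 and NMNAT3 were at -0.08 and -0.19. The ERBB2 call was lost without a filter on signal (-1.85, adjusted p = 0.0663), with quantile normalization (-1.85, adjusted p = 0.131) and with the mean over probe sets (-0.62, adjusted p = 0.352), over a range of 8.5e-08 to 0.352. With that mean PHTF2, PPP6C, ITSN2, NECTIN3, CYB5B, TFAP2A, ZNF544, NMNAT3 and NSUN5 lost their calls too (adjusted p of 0.0504 to 0.27), and TFAP2A also with quantile normalization (2.84, adjusted p = 0.0968). The comparisons of both estrogen forms share the vehicle array of a line, so their equal direction in these genes is no independent check.

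Of the lists fixed for testing, called members included the classical estrogen targets TFF1 (1.11, adjusted p = 0.0122, below the filter intensity on 4 of 5 HTB-182 arrays and 0.69 with those raised to it) and TGFA (1.64), the death receptor gene FAS (2.07), the chemokine gene CXCL1 (1.51, or 1.32 with the HTB-182 arrays, all below, raised likewise) and the squamous marker SOX2 (2.04). The chaperone gene HSPA5 (0.64, adjusted p = 0.00604) and the stress gene TRIB3 (-1.04, adjusted p = 0.0386) were called too. Without a filter on signal TFF1 lost its call at the same size (1.11, adjusted p = 0.0808, and 0.00483 or more under the other settings). With the mean over probe sets TGFA lost its own (0.47, adjusted p = 0.267, and 4.0e-06 or more otherwise), its other probe set being at -0.34, and so did FAS (0.44), SOX2 (0.229), HSPA5 (0.804) and TRIB3 (0.115). The other probe sets of FAS were at 0.0091, those of SOX2 at 0.31 and that of HSPA5 at -0.39. The HSPA5 call was also lost without a filter (0.64, adjusted p = 0.0528) and without the intensity trend (0.64, adjusted p = 0.225). That of TRIB3 was lost without a filter, with quantile normalization, with centring and with each probe set alone (-1.04 to -0.94, adjusted p of 0.0729 to 0.0872). CXCL1 kept its call under all settings run (adjusted p of up to 0.043). Camera called no list (smallest adjusted p 0.111, and 0.974 with an estimated correlation). Adjusted over the list alone 4 classical estrogen targets passed (3 over all genes), 3 NF-kB and cytokine genes (2), 3 G1/S genes (1), 2 apoptosis regulators (1) and 1 blood and endothelial marker (0), and the other lists had equal counts. HSPA5 and TRIB3 lost their calls without any 1 of the 4 arrays with tamoxifen (adjusted p of up to 0.0791 and 0.209), in fits whose spread comes from the arrays of estradiol and the conjugate without tamoxifen. In 180 called genes with other probe sets, these showed a median share of 0.0189 of the change, and with the mean over probe sets 37 genes passed. Quantile normalization gave 218 genes, 205 higher and 13 lower, and centring each array on its median 307, 290 higher and 17 lower. Without the HTB-182 estradiol array 2251 genes passed and without the A549 estradiol array 2290, with a spread from the arrays with tamoxifen alone, and no fit was possible without a vehicle array.

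The cell lines differed in 8526 genes by limma, 4367 higher and 4159 lower in A549, and 3154 genes differed at least 2-fold. Where all arrays of a line lay below the filter intensity of 19.7, that line was raised to it and the difference is given as a bound with the words at least. AMIGO2, an adhesion gene, was at least 199.8-fold higher in A549 (log2 at least 7.64), and AKR1B10, an aldo-keto reductase of the NRF2 targets, was 262-fold higher (adjusted p = 2.3e-13). Also higher were ANXA1 (7.01), KYNU (at least 7.15), TFPI2 (at least 6.87), the adenocarcinoma marker AGR2 (at least 6.92) and SRGN (at least 6.49). CAV1, the main caveolar protein gene, had an intensity of 3386 ± 323 (SD, n = 5) in A549 and lay below the filter intensity in HTB-182, a difference of at least 6.57. CXCL14 was at least 334-fold lower in A549. Lower by at least the size of the value were PTX3 (-6.55), MAL2 (-6.43), PTPRZ1 (-6.32), the cancer-testis gene MAGEA4 (-6.23) and the Wnt inhibitor gene WIF1 (-5.68). PRDX2 was at -6.96 as such a bound, while its other probe sets were at -0.71.

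NRF2 targets, genes of the antioxidant response, had the smallest p of all lists, with 24 of 24 higher in A549 (adjusted p = 5.3e-12, and 0.0286 with an estimated correlation), among them HMOX1 (5.43) and ABCC3 (6.30, its other probe sets at 1.03). ABCC3 was below the filter intensity on 4 of 5 HTB-182 arrays, and with those raised to it the difference was 6.22. The other calls of lists had an adjusted p of 0.206 or more with an estimated correlation. Of 19 p53 targets 16 were higher and 1 lower (adjusted p = 3.9e-05, and 0.206 with the estimated correlation), with CDKN1A at 3.80 and GDF15 at 3.60. Of 20 NF-kB and cytokine genes 15 were higher and 0 lower (adjusted p = 0.000447, and 0.206), with CXCL5 at 6.12 or more and PTGS2 at 5.04 or more. Estrogen receptors and partners had 12 of 19 higher and 1 lower (adjusted p = 0.00554, and 0.206), and glucocorticoid receptor targets 11 of 14 higher and 2 lower (0.00575, and 0.399). EGFR was at 3.80, with its other 7 probe sets at a median of 0.45. It lay below the filter intensity on 4 of 5 HTB-182 arrays, and with those raised to it the difference was 3.59. Autophagy and lysosome genes (16 higher and 5 lower of 23, 0.018), mesenchymal markers (9 and 2 of 14, 0.018) with VIM at 2.48, alveolar and adenocarcinoma markers (11 and 3 of 17, 0.019) with KRT7 at 6.64 (other probe set 0.26; 3 of 5 HTB-182 arrays below the filter intensity, and 6.52 with those raised to it), and apoptosis regulators (13 and 2 of 20, 0.019) were called higher. So were unfolded protein response chaperones (13 and 3 of 21, 0.0312) and aryl hydrocarbon receptor targets (5 and 1 of 7, 0.0466). With the estimated correlation the adjusted p of these 6 lists was 0.525 for the autophagy and the unfolded protein response lists and 0.206 for the other 4.

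Cell cycle genes were lower in A549. Of 27 G2/M genes 25 were lower and 0 higher (adjusted p = 4.9e-08), among them CDCA8 (-2.27), CDC20 (-2.08) and BUB1B (-1.92). Of 25 G1/S and replication genes 19 were lower and 3 higher (adjusted p = 0.000121), with MCM2 at -2.54, CCNE2 at -2.37 and GINS2 at -2.34 (its other probe sets at -0.38). With an estimated correlation the adjusted p was 0.206 for both cell cycle lists. Sterol synthesis and uptake genes were lower (10 lower and 2 higher of 19, adjusted p = 0.0226), with ACAT2 at -2.19 and INSIG1 at -1.05, and so were neuroendocrine markers (4 lower and 1 higher of 7, 0.0385), with CHGB at -4.14 and INSM1 at -3.28 as a bound. With an estimated correlation the adjusted p was 0.487 for both.

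The remaining lists were not called between the lines. Immediate early genes had 20 of 34 higher and 9 lower (adjusted p = 0.052). Classical estrogen targets had 18 of 33 higher and 10 lower (0.174), with CA12 at 6.96, IGFBP4 at 4.78 and MYB at -4.41 as a bound (its other probe set at -1.62). In HTB-182 CA12 was below the filter intensity on 1 of 5 arrays and IGFBP4 on 3 of 5, and with those raised to it the differences were 6.95 and 4.67. Hypoxia and glycolysis genes had 12 of 22 higher and 5 lower (0.184), the integrated stress response 14 of 30 and 7 (0.184), and liver X receptor targets and fatty acid synthesis 7 of 13 and 3 (0.241). Heat shock genes had 5 of 12 higher and 5 lower (0.768), with a median of -0.12 and a mean of 0.50. Blood and endothelial markers had 1 of 7 higher and 1 lower (0.768), and squamous markers 3 of 8 and 3 (0.834), with SOX2 at -4.92 and its other probe sets at -2.03. Adjusted over the list alone the counts of called members equalled those over all genes in all lists but 3, with 7 aryl hydrocarbon receptor targets, 18 hypoxia and glycolysis genes and 31 immediate early genes.

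Differences from vehicle were set against each other across the 12979 genes. The estradiol effect correlated between the lines at r = -0.0072 and the estradiol-BSA effect at -0.043. The difference between the estrogen forms correlated between the lines at 0.058, and the tamoxifen effect at 0.13 with estradiol and -0.11 with the conjugate. Effects of both estrogen forms within a line share the vehicle array. By simulation, with every array given the spread of the treated arrays of its line, sharing it alone gives r = 0.499 in HTB-182 and 0.497 in A549. The observed values were 0.60 and 0.73, with covariances of 0.0156 and 0.129 against simulated 0.0135 and 0.0336. With 1 vehicle array per line the controls could not be split, and part of the excess may come from them. The A549 vehicle array lay further from its line than the simulated spread (median 0.252 log2 units, against a median SD of 0.136). The simulated A549 values are thus too low, and the A549 excess cannot be told apart from an effect of that array. Comparisons with no array in common gave r = 0.19 and 0.33 in A549 (estradiol against vehicle with tamoxifen on the conjugate, and the conjugate against vehicle with tamoxifen on estradiol), and -0.097 and -0.14 in HTB-182, with simulated values near 0. The tamoxifen effects on estradiol and on the conjugate, also with no array in common, gave r = 0.15 in HTB-182 and -0.21 in A549 (covariances 0.00345 and -0.0104, simulated values near 0). In A549 the tamoxifen effect over both forms thus averages differences of single arrays that were negatively correlated across genes. The simulated noise was drawn for each gene separately, so it holds no structure that genes of an array share. Departures from the simulated values therefore do not show an effect of treatment, nor opposite effects of tamoxifen.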

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

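The tests of whole transcripts and of spike-in probe sets were chosen only after the result was seen, and so were the added requirements on the ratio of 3' to 5' control signals and on the number of spike-in probe sets.

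The test of the difference between the lines in the estrogen effect called 369 genes, with a spread that comes from the treated arrays alone, as the model fits each vehicle array exactly. Among the named genes A549 exceeded HTB-182 by 3.90 for ID2, 3.70 for ITSN2, 3.37 for PHTF2, 3.34 for PPP6C, 3.18 for FUNDC1, 3.11 for NECTIN3, 2.89 for CYB5B and 2.69 for TFAP2A on the log2 scale. The list members FAS (2.07), SOX2 (2.04), TGFA (1.64), CXCL1 (1.51), TFF1 (1.11) and HSPA5 (0.64) differed in that direction too. Differences in the opposite direction were -1.85 for ERBB2, -1.45 for ZNF544, -1.42 for NMNAT3, -1.26 for NSUN5 and -1.04 for TRIB3.

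The A549 vehicle array, on which these differences rest, was at least 2-fold from the mean of the other A549 arrays for 263 genes and lower in 249 of them. For these 263 genes scaling is argued against, as 96.6% of them (254) remained 2-fold apart after quantile normalization. That does not cover the 80 called genes with a lower value in A549. Quantile normalization and median centring left far fewer calls in that direction. The A549 vehicle array also had the highest median intensity (21.4), so scaling stays open for those calls. An admixture of HTB-182 RNA is argued against. The 200 genes with the largest HTB-182 excess (median 3.99) were higher on that array by only 0.089 (95% interval 0.050 to 0.13). A response of whole transcripts as the cause for the called genes as a set is also argued against, because their other probe sets showed a median share of 0.0189 of the change (interval -0.018 to 0.073, 180 genes), against 0.60 for the line difference, although shares were low in all treatment comparisons (-0.070 to 0.14) and 18 genes, among them TRIB3 and NSUN5 (0.70 each), had shares of 0.51 or more, against 6 genes with shares of -0.5 or lower. An effect of probe set position along the transcript, such as shorter labelled RNA, cannot be told apart from a failure of single probe sets: the other probe sets of the 139 genes showed a share of 0.0065 with 48.9% of opposite sign, but the actin 3' to 5' ratio (3.27) lay within that of the other A549 arrays (2.66 to 3.57) and that of GAPDH (1.43) just below theirs (1.45 to 1.61), while 3 of 45 spike-in probe sets departed from their own spike against up to 2 elsewhere, which is more than on any other array but too few to decide. An estrogen effect on single genes in A549 stays open and untested, since it rests on 1 vehicle array.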

How the results depend on the processing

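Quantile normalization of the gene lists, centring on the median and array quality weights were chosen after seeing the data. Of 141 results for named genes 140 had no reversed value. Over other settings 1440 values kept direction and side of the threshold, 10 gained and 25 lost a call, and over arrays left out 1309 did, with 49 gained and 8 lost. Values that stayed uncalled count as kept here. All lost calls were among the 19 named genes called for the line by estrogen term, so the totals do not show that this term is stable. The result with reversed values was the line difference of ESR2 (-0.0090), at 0.0013 with a pseudocount of 64 and at -0.13 to 0.073 over arrays left out. The cause was not tested.

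The 7 list calls in treatment comparisons became 0 with an estimated correlation and 3 with quantile normalization, and stayed 7 with median centring. The line by estrogen term (369) gave 218 genes with quantile normalization, 201 of them shared, and 37 with the mean of probe sets, 36 shared, when 15 of the 19 named genes lost their call. For the line difference (8526), 16841 probe sets passed when each was tested on its own, as 27307 were tested. Array quality weights, which were equal for both lines within a treatment, gave 1 gene (ID1) between the estrogen forms, 105 for the line by tamoxifen term, 2 (WASF3 and P3H1) for tamoxifen in HTB-182 and 11 in A549. For these counts the cause was not tested, except that more probe sets were tested.

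Genes 2-fold apart in both lines became 0 for estradiol-BSA against vehicle (1, ID1) with a pseudocount of 64 and with median centring, and 1 (BDKRB2, named after its values were seen) for tamoxifen on the conjugate with a pseudocount of 1. At 1.5-fold the counts were 2 for estradiol and 5 for estradiol-BSA against vehicle, 2 (ACTA2 and ZBED1) for tamoxifen on estradiol and 0 on the conjugate, as the lower limit admits smaller changes.

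With each array left out in turn, counts ran from 0 to 1078 for estradiol, 0 to 2058 for estradiol-BSA, 0 to 1754 for estradiol with tamoxifen and 0 to 2104 for the conjugate with tamoxifen, each against vehicle. The highest came without the HTB-182 vehicle array, when vehicle rests on the A549 array alone and this lone sample is assumed to vary like the other groups. They ran from 0 to 1 between the estrogen forms, 0 to 4 for the line by tamoxifen term, 0 to 3 for tamoxifen in HTB-182, 0 to 30 in A549, 7812 to 8755 for the line and 279 to 2290 for the line by estrogen term. The tamoxifen effect and its difference between the forms stayed at 0.

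Lines pair the arrays. With no replicate block, the cell line left out, all 7 treatment fits gave 0 genes by limma (18 to 85 at an unadjusted p under 0.05), and the line difference with treatment left out gave 8735. In those treatment fits the line difference entered the spread, so their low counts were largely fixed in advance and are no check. Paired differences of the 4 tamoxifen pairs gave 0 (512 unadjusted). Genes below the filter intensity of 19.7 were not tested. The brightest probe sets of ESR1, ESR2 and GPER1 lie close to it, and the means of their other probe sets lie below it.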

Other observations

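Within single lines the medians of the lists were placed among random lists of like expression. Of 230 such percentiles 25 lay below 2.5 or above 97.5, limits chosen after the values were seen. Chance gives 11.5 where genes and comparisons are independent, which they are not here, and camera with an estimated correlation left 0 treatment list calls, so the values describe these arrays only. When tamoxifen was added to estradiol in A549, G1/S and replication genes had a median of -0.25 (percentile 0.21, 5 of 25 above 0) and G2/M genes -0.23 (percentile 0.61, 7 of 27). With the conjugate the same medians were 0.04 and 0.03 (percentiles 62.8 and 37.0). Integrated stress response genes had a median of 0.09 when tamoxifen was added to the conjugate in A549 (percentile 99.7, 21 of 30 above 0). In HTB-182, sterol genes had medians of 0.12 and 0.07 when tamoxifen was added to estradiol and to the conjugate (percentiles 99.9 and 98.5), and aryl hydrocarbon receptor targets 0.16 with estradiol (percentile 99.8, 4 of 7 above 0). Heat shock genes in HTB-182 had 0 of 12 members above 0 after estradiol (median -0.07, percentile 2.15). These are differences between 2 arrays each, with no replicate check.

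The test of BMP targets over both pairs of a line and the requirement on the range of probe set shares were chosen only after the first result was seen, as were ID2, ID3 and ID4. With estradiol-BSA instead of estradiol, ID1 was at -1.33 in HTB-182 and -0.78 in A549 on the log2 scale, and with tamoxifen at -1.13 and -0.82. In A549 ID3 was at -1.19 and -1.06 and ID4 at -1.14 and -1.44, against -0.36 and -0.29, and -0.11 and -0.13, in HTB-182. ID genes are known BMP targets, so lower BMP signalling with the conjugate is a candidate explanation. The median of 16 other BMP targets was 0.11 in HTB-182 (95% interval 0.049 to 0.18, percentile 84.4) and 0.034 in A549 (-0.18 to 0.17, percentile 94.7), at odds with it and past the level set beforehand against it, a median of 0 or more in 1 line. That level was not the one random lists of like expression give, which had a median of 0.069 in the same HTB-182 pair and -0.11 in that of A549. Set against these, the list lay higher in both lines, in A549 by more than against 0, which goes against the explanation, but both intervals include the random median. The pairs with tamoxifen put the list lower, at percentiles 22.1 (median 0.013) and 15.1 (-0.094), so the explanation is neither excluded nor borne out. The 4 other probe sets, 1 of ID2 and 3 of ID4, showed a median share of 0.67 of the change (0.41 to 0.74), while ID1 and ID3 have no other probe set, so an effect of probe set position cannot be told apart from it. An effect of the albumin itself and a difference in handling between arrays of the free and the conjugated form are confounded with the treatment.

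Other splits of the arrays were tested for both comparisons with at least 4 arrays per side. For tamoxifen the real count was 0, which 35 of 35 splits of the 8 estrogen arrays reach by construction, so they say nothing about chance. The highest other count was 8942, from the split by line, which points to the line as a structure of the samples, and 36 was the highest among splits that do not follow the line. Among the 8 splits that part all 4 pairs the highest other count was 0. For the line difference 1 of 100 splits, the real one, gave as many as 8526 genes, and the highest other count was 0. The models of the other splits held no term for the cell line, so the line difference entered their spread. Low counts were thus largely fixed in advance, and these splits cannot decide about chance either.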
